A study of Gallus gallus with 8 samples.

How the data were processed

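Messenger RNA was sequenced from the hearts of chicken embryos at 16 days of incubation. There were 8 libraries from 4 breeds, 2 per breed. Linzhi Tibetan and Lhasa White carry the names of places on the Tibetan plateau and were treated as highland breeds (4 libraries). Chahua, from southern China, and White Leghorn, a commercial layer line, were treated as lowland breeds (4 libraries). Breed was taken from the labels. The labels do not say whether the libraries of a breed came from separate embryos, so p-values measure the spread between these libraries, which may be partly technical. ATP5A1W, a gene of the female-specific W chromosome, lay at 4.02 and 398 RPKM in Lhasa White and at 409 and 0.241 in White Leghorn. This argues against repeats of the same sample in those breeds, and leaves it open in Linzhi Tibetan and Chahua. The labels give no sex. Altitude and oxygen during incubation were not among the labels used here, so a difference in them between breeds cannot be excluded.

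RNA was extracted with TRIzol and libraries were made with an Illumina mRNA kit, per the labels' protocols. The deposited table holds RPKM values, read numbers scaled to the length of the gene model and to the mapped reads of the library, for 15873 Ensembl gene identifiers, per the file headers. BWA is named in the submitters' processing notes without a version. The genome build, the gene models, the counting step, the filters and the use of strand are not given in the sources used here. Symbols were those of the table, where 2730 genes have none. The chromosome of a gene was looked up by symbol in the GRCg7b gene table for 12229 genes and used only to mark 588 Z-linked genes and the W-linked genes. No coordinates were used, because the build of the deposited values is not given.

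Depth was recovered from the RPKM values themselves. Within a gene, the values of the 8 libraries are whole multiples of what 1 read is worth. With library totals fitted to this rule, 100% of genes gave whole reads in every library within a tolerance of 0.05 reads, against 0 of 1000 control genes with shifted depths. The control genes were nonzero in all 8 libraries with a mean RPKM of at least 1, so these rates cover unlike genes. The main search also allowed a wider second pass, which the control did not. The fitted totals were 17245669 mapped reads in the shallowest library and 22157553 in the deepest. The median gene past the filter had 456 reads per library, averaged over the libraries. Reads shared between paralogs, overlapping genes or antisense partners cannot be told apart in these values.

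Genes with RPKM of at least 1 in at least 2 libraries were tested (11556 genes). Values were transformed to log2(RPKM + 1), so that log2 differences understate the change of low genes. A linear model with 1 mean per breed was fitted to all 8 libraries in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and a variance trend. It had 4 residual degrees of freedom. Contrasts were the mean of both highland breeds minus the mean of both lowland breeds, each of the 6 breed pairs, and the other pairings of breeds. A moderated F test covered any difference among breeds. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the read recovery, checks and plots.

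Gene lists for pathways and cell types were fixed before the data were examined. Of these, 25 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Adjustment was over the 25 lists within a contrast. The liver and lung lists had fewer members past the filter and were only described, as was the list of W-linked genes.

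The genes named in the text followed a rule fixed before the data were examined. It takes the largest differences among passing genes and, where fewer than 5 pass, the 10 genes with a symbol and the smallest p. EPAS1, HIF1A, EGLN1, VHL and VEGFA are always named, as are up to 4 members per list with the smallest p between highland and lowland breeds. Which of those 4 members the text names was decided after their values were seen. VHL has no row under that symbol and is not analysed here. The values of 1 other gene are not reported. Genes named outside this rule are said to be chosen after their values were seen.

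The procedure was tested on simulated libraries with the real means and depths of 11556 genes and with their moderated spreads from the fit. Of 100 genes changed 2-fold between highland and lowland breeds, 82 were recovered, and of 100 changed 4-fold, 98 were. There were 7 calls among unchanged genes, and 0 calls in a simulation without changes. Changed genes had mean RPKM of at least 5. Apart from these changes, each gene varied independently around a mean shared by all breeds. The simulation thus lacked the sex-linked and heart chamber differences of the real libraries, where recovery may be lower.

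Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median ratio scaling, quantile normalization, other variance models (robust moderation used statmod 1.5.0), the replicate number as a block, a 2-fold minimum, the removal of Z and W genes, each library left out in turn, smaller sets of samples and other set tests. Added after seeing the data were the W-linked level as a covariate, fits within libraries that share W-linked status, voom on the recovered reads, the removal of 2 libraries with atrial transcripts, and rescaling without mitochondrial and hemoglobin genes. The W-linked level was the mean log2(RPKM + 1) of the ATP5A1W, HINTW and SPINW rows. Within breeds it differed mainly between the libraries of Lhasa White and of White Leghorn, so the covariate rests on these. Lhasa White 2 also holds atrial transcripts, so in Lhasa White the covariate cannot be told apart from heart chamber tissue.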

Results

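Heart transcriptomes of 16-day embryos were compared between 2 breeds of the Tibetan plateau and 2 lowland breeds, with 2 libraries per breed. The series pairs this RNA sequencing with a search for genes under selection in highland chickens. Mapped reads ranged from 17245669 in Chahua 1 to 22157553 in Linzhi Tibetan 2. Between 10795 and 11311 genes reached 1 RPKM in a library. Pearson correlations of log2 values were 0.952 to 0.983 between libraries of one breed and 0.937 to 0.984 between libraries of different breeds, so the ranges overlapped. The first principal component held 33.7% of the variance and separated Lhasa White 2 and Chahua 2 from the other 6 libraries.

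The libraries differed in the sex-linked transcripts they held. ATP5A1W, a gene of the female-specific W chromosome, lay at 398 RPKM in Lhasa White 2, 445 in Chahua 1, 496 in Chahua 2 and 409 in White Leghorn 1. It was at 4.02 RPKM in Lhasa White 1 and at or below 0.355 in both Linzhi Tibetan libraries and White Leghorn 2. HINTW and SPINW followed the same division. The median Z-linked gene went the other way, from -0.28 to -0.05 on the log2 scale in the 4 libraries with W-linked transcripts and from 0.09 to 0.21 in the other 4. Thus 1 of 4 highland and 3 of 4 lowland libraries held W-linked transcripts. Both Linzhi Tibetan libraries lacked them and both Chahua libraries held them, so this signal cannot be separated from breed in comparisons of that pair.

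Heart chamber transcripts also differed between libraries. MYH7, the atrial myosin heavy chain of the chicken, lay at 1457 RPKM in Lhasa White 2 and 115 in Chahua 2, against 0.878 to 7.07 in the other libraries. BMP-10, an atrial growth factor, lay at 290 RPKM in Lhasa White 2 and 22.4 in Chahua 2, against 0.745 to 3.93 elsewhere. MYH15, a ventricular myosin, was at 1288 RPKM in Lhasa White 2 and at 3198 to 4949 in the others. IRX4, a ventricular transcription factor, was at 16.2 RPKM in Lhasa White 2 and at 61.7 to 90.9 in the others. ELN, the elastin of arterial walls, was at 1468 RPKM in Lhasa White 2 and 67.5 to 157 in the others. MYH7, BMP-10 and ELN were chosen after their values were seen. HBAA, an adult-type alpha globin and a marker of blood, ranged from 3898 RPKM in Linzhi Tibetan 1 to 16344 in Lhasa White 1. Hemoglobin genes took 0.521% to 2.18% of mapped reads.

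**Figure D1:**
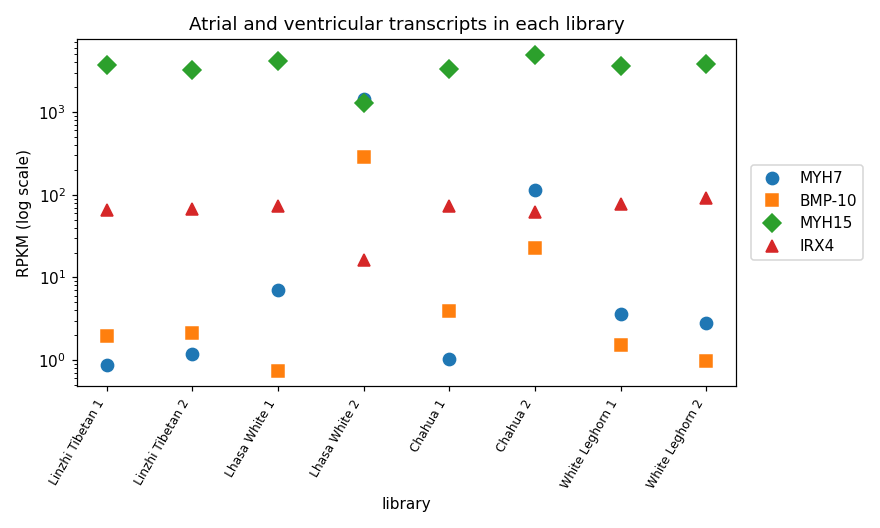
RPKM (log axis) of the atrial transcripts MYH7 and BMP-10 and the ventricular transcripts MYH15 and IRX4, with 1 point per library. Lhasa White 2 has MYH7 at 1457 and IRX4 at 16.2, and Chahua 2 has MYH7 at 115, while the other libraries have MYH7 at 7.07 or less.

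The comparison of highland with lowland breeds asked which heart transcripts differ between these groups of breeds. With 2 breeds on each side, altitude of origin cannot be separated from breed. The p-values rest on the spread between libraries within breeds, so they speak of these breeds and not of highland breeds in general. GBP (ENSGALG00000026152), a guanylate-binding protein of the interferon-induced family, was the gene that differed. Its level was 2.22 ± 1.69 RPKM in highland and 13.5 ± 4.39 in lowland libraries (SD, n = 4 each), a log2 difference of -2.27 (SE 0.165, limma adjusted p = 0.0204). All 4 highland libraries lay below all 4 lowland ones. GBP was at 0.901 and 0.895 RPKM in Lhasa White, 2.65 and 4.43 in Linzhi Tibetan, 18.8 and 15.3 in Chahua, and 10.6 and 9.17 in White Leghorn. The call was lost when any library except Linzhi Tibetan 2 was left out, with adjusted p of 0.0895 without Linzhi Tibetan 1, 0.0885 and 0.0857 without Lhasa White 1 or 2, 0.254 and 0.174 without Chahua 1 or 2, and 0.205 and 0.178 without White Leghorn 1 or 2 (log2 differences of -2.41 to -2.12 over the 8 omissions). It was also lost without both libraries with atrial transcripts (-2.33, adjusted p = 0.252), with the W-linked level as a covariate (-2.21, adjusted p = 0.239), with the replicate number as a block (adjusted p = 0.105), without the low-value filter (adjusted p = 0.0799), with voom on recovered reads (-2.86, adjusted p = 0.0576) and with 2 groups of 4 in place of breed means (adjusted p = 0.999). Within the 4 libraries with W-linked transcripts GBP did not pass (-3.04, adjusted p = 0.282), nor within the other 4 (-1.60, 0.999). Where breed means were fitted, adjusted p over the alternatives ran from 0.0158 to 0.254.

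**Figure D2:**
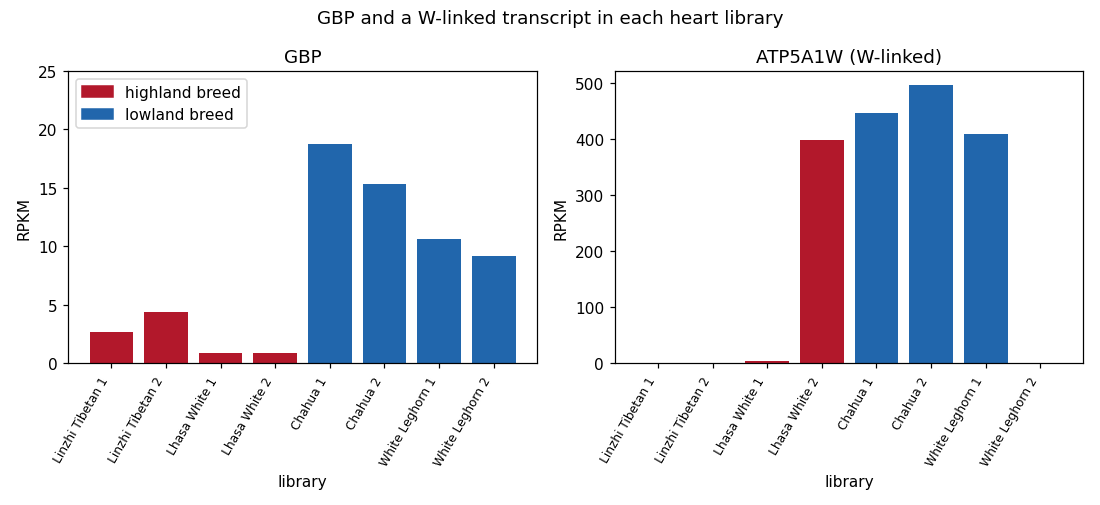
RPKM of GBP (left) and of the W-linked ATP5A1W (right), with 1 bar per library, coloured by breed origin. GBP is at 4.43 or less in each highland library and at 9.17 or more in each lowland library, while ATP5A1W divides the libraries differently.

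No other gene passed between highland and lowland breeds in the limma test of 11556 genes. At an unadjusted p under 0.05 there were 362 genes, against 578 expected by chance, and voom gave 0 adjusted calls and 331 at that p. The next smallest p-values belonged to ABCC9, a subunit of ATP-sensitive potassium channels, at 9.94 ± 2.07 RPKM in highland and 26.5 ± 15.1 in lowland libraries (adjusted p = 0.485), and C14orf80 at 16.2 ± 3.28 and 43.5 ± 28.3 RPKM (SD, n = 4, adjusted p = 0.495). ABCC9 lay at 44.5 and 33.5 RPKM in White Leghorn and at 12.9 and 15.2 in Chahua, while C14orf80 lay at 17.3 and 21.1 RPKM in White Leghorn and at 64.0 and 71.8 in Chahua. IL17RD, an FGF signalling inhibitor, LAMA1, a laminin chain, KLHL23, the kinase gene DAPK2 and the class II histocompatibility gene DMB2 had log2 differences of -0.98, -1.24, -0.82, -0.62 and -0.85. BMP3, of the bone morphogenetic protein family, had one of 1.02, and gga-mir-1b, a muscle microRNA precursor, 0.57. The adjusted p-values of these genes lay between 0.541 and 0.703. BMP3 lay at 11.7 and 13.3 RPKM in Lhasa White but at 3.49 and 3.93 in Linzhi Tibetan, against 1.85 to 4.03 in lowland libraries. IL17RD lay at 0.993 and 1.10 RPKM in Linzhi Tibetan and 4.05 and 2.71 in Lhasa White, against 4.25 to 5.90. The microRNA lay at 24.8 and 20.5 RPKM in Lhasa White and at 23.4 and 20.7 in White Leghorn. The groups did not overlap in 108 genes higher and 69 lower in highland libraries, 0.935% and 0.597% of genes, where chance gives 1.43% each way.

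Genes of the oxygen-sensing pathway did not pass. EPAS1, the hypoxia-inducible factor HIF-2 alpha, was at 52.3 ± 6.75 RPKM in highland and 50.9 ± 8.46 in lowland libraries (SD, n = 4). HIF1A was at 14.6 ± 2.45 and 12.97 ± 3.54 RPKM. EGLN1, the oxygen-sensing hydroxylase that marks these factors for degradation, was at 20.6 ± 2.39 and 21.3 ± 3.70 RPKM. VEGFA, the vascular growth factor, was at 86.6 ± 22.0 and 92.6 ± 10.97 RPKM. Their log2 differences were 0.04, 0.18, -0.04 and -0.13, with standard errors of 0.1 to 0.197 and adjusted p of 0.999 each. Of 15 measured members of the pathway list, 9 were higher and 6 lower, and 0 passed. Of 34 hypoxia-induced genes, 14 were higher and 20 lower, and 0 passed, also when adjusted over the list alone. Among them, STC2 lay at 17.2 ± 2.86 and 11.04 ± 1.78 RPKM, HK2, which starts glycolysis, at 9.36 ± 0.704 and 6.44 ± 2.11, and EDN1, the vasoconstrictor endothelin precursor, at 7.10 ± 1.41 and 5.39 ± 1.99 (SD, n = 4). Neither list passed camera (adjusted p = 0.767 for each), and the hypoxia-induced list had a median of -0.03 but a mean of 0.02.

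Of the 25 fixed lists, 7 passed camera at its preset correlation, and 0 passed with an estimated correlation or with fry's test for one direction. At the preset correlation the other pairings of the breeds gave 9 and 10 lists, and single breed pairs gave 6 to 9. The count of 7 is thus not particular to the highland and lowland grouping. Fry's test for change in either direction passed for 2 lists, glycolysis and smooth muscle (adjusted p = 0.0217 each). Of 54 nuclear genes of oxidative phosphorylation, 47 were lower in highland libraries, with a median log2 difference of -0.09 (adjusted p = 6.86e-05, and adjusted p = 0.766 with an estimated correlation). Examples are NDUFA10 and NDUFA8, complex I subunits, at 131 ± 8.67 and 134 ± 17.1 RPKM in highland against 147 ± 6.62 and 158 ± 17.8 in lowland libraries. Of 19 glycolysis genes, 15 were lower (median -0.14, adjusted p = 0.0041, and 0.683 with an estimated correlation), with LDHB, a lactate dehydrogenase, at 551 ± 51.9 and 919 ± 478 RPKM. In this list 2 genes reached an unadjusted limma p under 0.05, LDHB and HK2. HK2 had the smaller p of these and went the other way, with a log2 difference of 0.52 (limma adjusted p = 0.999). LDHB was at 1631 RPKM in White Leghorn 1, and its log2 difference was -0.62 with and -0.33 without that library. Of 27 genes of fatty acid oxidation, 16 were lower (median -0.07, adjusted p = 0.0429, and 0.766 with an estimated correlation), with ETFDH at 46.1 ± 5.65 and 55.8 ± 5.62 RPKM. Of 60 ribosomal protein genes, 51 were higher (median 0.07, adjusted p = 0.00174, and 0.766 with an estimated correlation), with RPL15 at 524 ± 42.9 and 433 ± 44.7 RPKM. With quantile normalization the ribosomal median was 0.04 (camera adjusted p = 0.0082). The rise of ribosomal proteins lay in Linzhi Tibetan alone, with 57 of 60 genes higher than in Chahua (median 0.20, adjusted p = 4.75e-09) and 58 of 60 higher than in White Leghorn (0.18, 8.06e-10). In Lhasa White 36 of 60 were lower than in Chahua (-0.04, 0.0399) and 43 of 60 lower than in White Leghorn (-0.04, 0.0379). Oxidative phosphorylation passed in Lhasa White against Chahua (-0.15, 2.12e-06) and White Leghorn (-0.09, 0.00321), but not in Linzhi Tibetan (-0.11, 0.0562, and -0.02, 0.742). Its list mean, relative to all libraries, was 0.09 in Lhasa White 1 and -0.23 in Lhasa White 2, against 0.00 to 0.07 in lowland libraries. The lower level in Lhasa White thus lay in library 2 alone. Fatty acid oxidation passed only in Lhasa White against Chahua (-0.11, 0.00251), and glycolysis in none of these 4 pairs. The fatty acid oxidation mean was 0.09 in Lhasa White 1 and -0.23 in Lhasa White 2, against 0.03 and 0.11 in Chahua, so that call rested on library 2. With an estimated correlation the adjusted p of these lists in the 4 pairs was 0.478 or more. Single members of these lists did not pass. The oxidative phosphorylation call was lost without Linzhi Tibetan 1 (median 0.00, adjusted p = 0.46), Lhasa White 2 (-0.02, 0.754), Chahua 1 (-0.07, 0.105) or both libraries with atrial transcripts (-0.02, 0.129), and its median was -0.18 without Linzhi Tibetan 2 and -0.15 without Lhasa White 1. The glycolysis call was lost without Linzhi Tibetan 1 (0.0676), Lhasa White 2 (0.0718) or Chahua 1 (0.563), that of fatty acid oxidation without Linzhi Tibetan 2 (0.149), Lhasa White 2 (0.958), Chahua 1 (0.489), White Leghorn 2 (0.112), both libraries with atrial transcripts (0.805), with median ratio scaling (0.0623), with quantile normalization (0.0867) or without the low-value filter (0.0532), and that of ribosomal proteins without Linzhi Tibetan 1 (0.0676), Lhasa White 1 (0.254), Chahua 1 (0.102) or White Leghorn 2 (0.0818). Over the omissions of single libraries the median ran from -0.18 (without Chahua 2) to -0.08 (without Chahua 1) for glycolysis, from -0.14 (without Lhasa White 1) to 0.00 (without Lhasa White 2) for fatty acid oxidation and from 0.02 (without Chahua 1) to 0.12 (without Chahua 2) for ribosomal proteins, which stood at 0.13 without both libraries with atrial transcripts.

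Markers of other cell types gave the remaining passing lists. Of 30 fibroblast and matrix genes, 27 were higher in highland libraries (median 0.18, adjusted p = 0.014, and 0.812 with an estimated correlation). LOX, a collagen cross-linking enzyme on the Z chromosome, was at 69.6 ± 20.4 and 46.7 ± 8.33 RPKM, and TIMP3 at 16.5 ± 2.90 and 13.9 ± 4.46. The log2 difference of LOX was 0.54 with all libraries and 0.17 without the 2 with atrial transcripts. The mean of this list was 1.09 above the mean of all libraries in Lhasa White 2, and without the 2 libraries with atrial transcripts its direction turned, with a median of -0.07 (adjusted p = 0.00652). It also turned without Lhasa White 2 alone (median -0.09, adjusted p = 0.0883), its median was 0.42 without Lhasa White 1 or with the W-linked covariate, and the call was lost without Linzhi Tibetan 1 (median 0.14, adjusted p = 0.25), Chahua 2 (0.23, 0.411) or White Leghorn 2 (0.16, 0.0525). By breed, matrix genes were higher in Lhasa White than in Chahua (0.34, 0.0081) and White Leghorn (0.70, 4.74e-12), while in Linzhi Tibetan 26 of 30 were lower than in Chahua (-0.35, 0.00294) and the list did not pass against White Leghorn (0.01, 0.652). With an estimated correlation these 3 calls had adjusted p of 0.727, 0.725 and 0.756. The matrix mean in Lhasa White 1 was -0.17, below Chahua (0.10 and 0.11) and above White Leghorn (-0.26 and -0.34). The higher level against Chahua thus lay in Lhasa White 2 alone. The W-linked covariate draws on the same difference between the Lhasa White libraries, so the median with it cannot be read as sex alone. Of 22 endothelial genes, 17 were higher (median 0.12, adjusted p = 0.0341, and 0.683 with an estimated correlation), with FLI1 at 39.4 ± 1.67 and 32.8 ± 2.08 RPKM and TEK, a Z-linked angiopoietin receptor, at 5.48 ± 0.986 and 3.98 ± 1.14. Of 14 smooth muscle and pericyte genes, 9 were lower (median -0.08, adjusted p = 0.0341, and 0.683 with an estimated correlation). In that list ABCC9 passed when adjusted over the list alone, and PDGFRB was at 13.4 ± 1.89 and 16.1 ± 2.04 RPKM (SD, n = 4 each). Smooth muscle genes were lower in Linzhi Tibetan alone, with 11 of 14 lower than in Chahua (-0.35, 0.00236) and 11 of 14 than in White Leghorn (-0.13, 0.0168). In Lhasa White 7 were higher and 7 lower than in Chahua (-0.01, 0.713), and 10 of 14 were higher than in White Leghorn (0.15, 0.564). With an estimated correlation the adjusted p of smooth muscle genes in Linzhi Tibetan was 0.549 against Chahua and 0.478 against White Leghorn. Their mean was -0.29 and -0.24 in Linzhi Tibetan, -0.06 in Lhasa White 1 and 0.37 in Lhasa White 2, so the Lhasa White libraries disagreed. Endothelial genes passed only in Linzhi Tibetan against Chahua (0.18, 0.00236, and 0.549 with an estimated correlation). In Lhasa White 13 of 22 were lower than in White Leghorn (-0.09, 0.391). The endothelial call was lost in 6 of the 8 omissions of a library and the smooth muscle call in 5, with adjusted p up to 0.218 (without Chahua 2, median 0.09) and 0.56 (without Lhasa White 1, median -0.01). Endothelial medians over the omissions were 0.09 to 0.15. The endothelial call was also lost without the low-value filter (median 0.12, adjusted p = 0.0507), at a mean RPKM of at least 5 (0.12, 0.0594), with median ratio scaling (0.10, 0.0504) and without both libraries with atrial transcripts (0.07, 0.173), and the smooth muscle call without the filter (-0.08, 0.0507), with quantile normalization (-0.11, 0.0737) and with the W-linked covariate (median -0.01, 0.213). The smooth muscle median was -0.27 (0.000665) without Lhasa White 2, -0.21 (1.71e-05) without both libraries with atrial transcripts and -0.14 without Linzhi Tibetan 2.

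The other lists did not pass between highland and lowland breeds with all libraries, but some passed when libraries or genes were left out, and 3 of them in both directions. Erythroid genes were higher in highland libraries without Linzhi Tibetan 1 (median 0.31, adjusted p = 0.00169) and lower without Linzhi Tibetan 2 (-0.25, 6.89e-05) or Lhasa White 1 (-0.14, 0.0409). Mitochondrially encoded genes were higher without Chahua 1 (0.26, 0.013) and lower without Chahua 2 (-0.27, 1.21e-06) or both libraries with atrial transcripts (-0.28, 6.33e-05). Proliferation genes were higher without Chahua 1 (0.14, 0.00499) and lower without Chahua 2 (-0.14, 9.96e-09), Linzhi Tibetan 2 (-0.08, 0.004), Lhasa White 1 (-0.05, 0.0395) or both libraries with atrial transcripts (-0.10, 4.69e-05). Cholesterol synthesis genes were lower without Lhasa White 2 (-0.23, 6.65e-04) or both libraries with atrial transcripts (-0.12, 0.00183). Chaperone genes were lower without Linzhi Tibetan 1 (-0.05, 0.042), antioxidant genes lower without Z and W genes (-0.05, 0.045) and immediate early genes higher without Chahua 1 (0.16, 0.0458). With all libraries the camera adjusted p-values were 0.405 for mitochondrially encoded genes, 0.162 for calcium handling, 0.201 for contractile genes, 0.618 for chamber regional genes, 0.682 for erythroid genes, 0.139 for angiogenic ligands and receptors, 0.265 for epicardial genes, 0.774 for leukocyte and thrombocyte genes and 0.917 for skeletal muscle genes. They were 0.162 for proliferation, 0.618 for DNA repair, 0.112 for antioxidant, 0.767 for interferon, 0.0965 for immediate early, 0.0897 for chaperone and 0.162 for cholesterol synthesis genes. Camera ranked calcium handling, erythroid and leukocyte genes lower while their median log2 differences were 0.04, 0.00 and 0.01. These p-values use the preset correlation of 0.01. The estimate with all libraries was 0.631 for erythroid, 0.518 for proliferation, 0.379 for mitochondrially encoded and 0.374 for cholesterol synthesis genes. With it, camera adjusted p was 0.844 to 0.9 for these lists, so the small p-values above are likely too small. XPA, which recognises ultraviolet damage in nucleotide excision repair, was at 70.6 ± 24.4 RPKM in highland and 49.4 ± 21.8 in lowland libraries (SD, n = 4). XPA is Z-linked, as is RPS23, which was at 1602 ± 469 and 1041 ± 349 RPKM. With the W-linked covariate the log2 difference of XPA was 0.18 in place of 0.52 and that of RPS23 0.21 in place of 0.61. Of 20 liver genes in the table, 3 passed the filter. ALB lay at 0.221 to 2.77 RPKM and the highest was APOA1, a lipoprotein gene, at 70.5 to 314 RPKM. Of 7 lung and airway genes, 4 passed, and the highest was the keratin gene KRT18 at up to 22.2 RPKM.

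The breed comparisons asked which of the 4 populations differ. In the moderated F test 0 genes passed, with 753 at an unadjusted p under 0.05 and 578 expected. Between Lhasa White and Chahua 1 gene passed. This was GBP, at 0.898 ± 0.00395 and 17.0 ± 2.46 RPKM (SD, n = 2, log2 difference -3.24, SE 0.233, limma adjusted p = 0.0188). That call held without either Linzhi Tibetan library (adjusted p = 0.0299 and 0.0326) and was lost without Lhasa White 1 (0.0576), Lhasa White 2 (0.0934), Chahua 1 (0.101), Chahua 2 (0.187), White Leghorn 1 (0.092) or White Leghorn 2 (0.0925), while the log2 difference over these omissions was -3.38 to -3.10. The call was also lost with the replicate number as a block (-3.24, adjusted p = 0.0975), with the W-linked covariate (-3.19, 0.0769), without both libraries with atrial transcripts (-3.38, 0.283), with voom and with only the 4 libraries of the pair. The other pairs gave 0 genes each in limma and in voom. At an unadjusted p under 0.05 there were 902 genes between Linzhi Tibetan and Lhasa White, 816 between Linzhi Tibetan and Chahua, 710 between Linzhi Tibetan and White Leghorn, 599 between Lhasa White and Chahua, 467 between Lhasa White and White Leghorn, and 910 between Chahua and White Leghorn. The other pairings of the breeds also gave 0 genes, with 1013 and 855 at an unadjusted p under 0.05, and voom gave 0 in each of them and in the F test.

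Gene lists marked some breeds. Cholesterol synthesis genes were lower in Chahua than in White Leghorn, with a median log2 difference of -0.62 over 19 genes, of which 13 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.14e-10, and 0.67 with an estimated correlation). FDFT1, the squalene synthase, was at 6.56 ± 0.138 RPKM in Chahua and 13.3 ± 1.13 in White Leghorn, and PMVK at 14.2 ± 2.51 and 22.2 ± 0.664 (SD, n = 2, adjusted p = 0.413 and 0.486). The list was also lower in Linzhi Tibetan than in White Leghorn (19 of 19 genes lower, 7 passing over the list alone, median -0.46, camera adjusted p = 1.8e-08, and 0.478 with an estimated correlation). It was lower in Lhasa White than in White Leghorn as well (15 of 19 lower, median -0.28, camera adjusted p = 1.49e-04, and 0.725 with an estimated correlation), and within Lhasa White its mean was 0.36 in library 2 and -0.13 in library 1. Other lists moved between Chahua and White Leghorn at the preset correlation. Proliferation genes (36 of 37 lower, median -0.43, adjusted p = 9.48e-09) and erythroid genes (17 of 20 lower, -0.67, 9.2e-04) were lower in Chahua. Hypoxia-induced genes (23 of 34 higher, 0.19, 0.00102), matrix genes (25 of 30 higher, 0.49, 0.0011) and contractile genes (22 of 33 higher, 0.17, 0.0188) were higher there. With an estimated correlation the adjusted p of these 5 lists was 0.67 to 0.788. The Chahua libraries differed from each other, with proliferation means of 0.07 and -0.46 and contractile means of -0.10 and 0.34 in Chahua 1 and 2, against 0.25 and 0.17, and -0.09 and -0.14, in White Leghorn. Without Chahua 2 the proliferation call was lost (median -0.18, adjusted p = 0.0774), the contractile median was 0.03 (0.0318) and the hypoxia-induced median 0.12 (2.24e-04). Without Chahua 1 the calls of contractile (median 0.41, adjusted p = 0.149), erythroid (-0.52, 0.205), matrix (0.45, 0.373) and hypoxia-induced genes (0.32, 0.166) were lost, and the proliferation median was -0.68 (8.28e-14). Without both libraries with atrial transcripts the calls of contractile (0.03, 0.145) and proliferation genes (-0.18, 0.113) were lost, without the low-value filter that of contractile genes (0.17, 0.0733), and with the W-linked covariate that of matrix genes (0.09, 0.372). Chaperone genes were lower in Linzhi Tibetan than in Lhasa White, with 27 of 35 lower, a median of -0.22 and 4 passing over the list alone (camera adjusted p = 2.46e-04, and 0.478 with an estimated correlation). HSP90AA1 was at 75.2 ± 16.9 RPKM in Linzhi Tibetan and 204 ± 17.7 in Lhasa White, and HSPA8 at 90.7 ± 2.49 and 192 ± 13.2 (SD, n = 2, adjusted p = 0.291 and 0.243). In the same pair matrix genes (28 of 30 lower, median -0.74, camera adjusted p = 1.69e-07), leukocyte genes (14 of 16 lower, -0.43, 2.67e-04), smooth muscle genes (12 of 14 lower, -0.32, 0.012) and cholesterol synthesis genes (17 of 19 lower, -0.28, 0.0313) were lower in Linzhi Tibetan, and ribosomal protein genes (58 of 60 higher, 0.23, 3.59e-15) were higher. With an estimated correlation the adjusted p of these lists was 0.478 to 0.682, and Lhasa White 2 stood at 1.09 in matrix genes against -0.17 in Lhasa White 1. Without Lhasa White 2 the calls of matrix (median -0.15, adjusted p = 0.151), smooth muscle (-0.14, 0.147) and cholesterol synthesis genes (-0.04, 0.792) were lost, as they were without both libraries with atrial transcripts (-0.15, 0.16, then -0.14, 0.16, and -0.04, 0.737). The cholesterol synthesis call was also lost without Linzhi Tibetan 1 (-0.20, 0.22), with the W-linked covariate (-0.10, 0.226), at a mean RPKM of at least 5 (-0.14, 0.086) and without the low-value filter (-0.25, 0.0564), and its median was -0.50 without Lhasa White 1. The matrix median was -1.29 (1.55e-20) without Lhasa White 1 and -0.38 (9.78e-04) with the covariate. Between Linzhi Tibetan and Lhasa White the leukocyte median was -0.24 without the low-value filter and -0.70 with a pseudocount of 0.1. The ribosomal protein median in that pair was 0.12 with quantile normalization (camera adjusted p = 0.00535). FDFT1, and the use of PMVK, HSP90AA1 and HSPA8 in these pairs, were chosen after their values were seen.

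**Figure D3:**
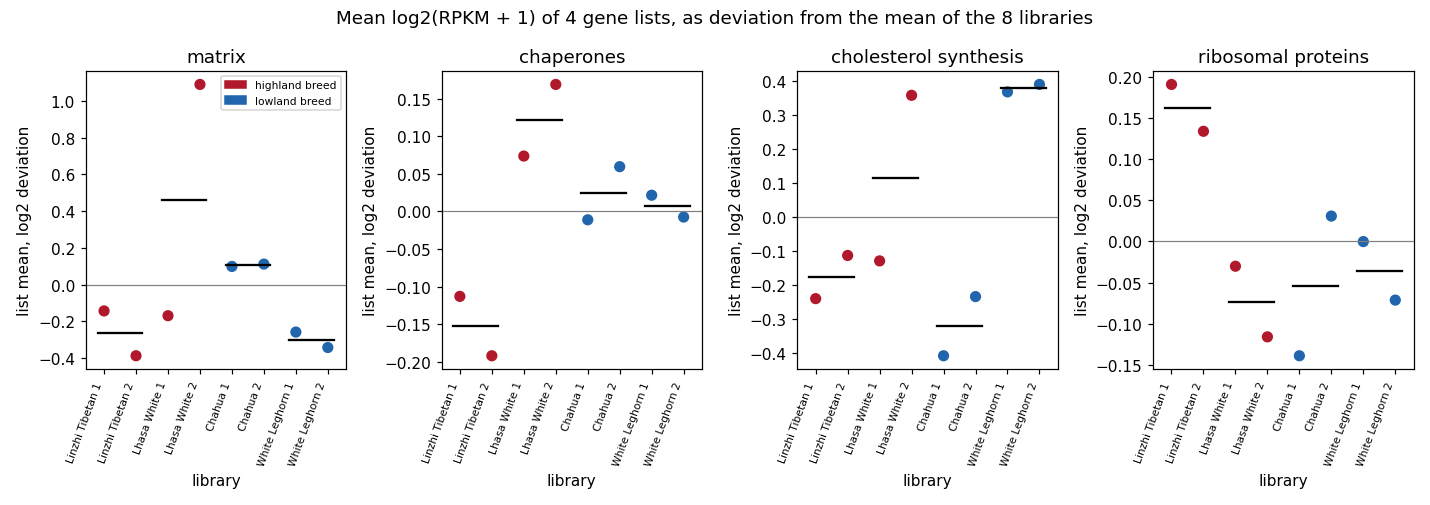
Mean log2(RPKM + 1) of 4 gene lists in each library, as deviation from the mean of the 8 libraries, coloured by breed origin; black lines are breed means of 2 libraries. Matrix genes reach 1.09 in Lhasa White 2, and cholesterol synthesis genes lie at 0.37 and 0.39 in White Leghorn against -0.41 and -0.23 in Chahua.

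Comparisons that share no library were set side by side to see whether both highland breeds differ from a lowland breed in like ways. Across 11556 genes, the log2 differences of Linzhi Tibetan minus Chahua and Lhasa White minus White Leghorn had r = -0.268 and Spearman rho = -0.288, with 39.75% of genes of the same sign (across genes, which are not independent replicates). For Linzhi Tibetan minus White Leghorn with Lhasa White minus Chahua r was -0.159 and rho -0.283, with 38.09% of the same sign. The arrangement that does not follow altitude, Linzhi Tibetan minus Lhasa White with Chahua minus White Leghorn, had r = -0.108 but rho = 0.0151, with 51.37% of the same sign. At an unadjusted p under 0.05, 22 and 24 genes were shared in the same direction in the altitude arrangements, where independent lists share 17.3 and 17.5, and 83 and 89 were shared in opposite directions, where independent lists share 15.7 and 19.3. In the other arrangement 77 were shared in the same direction and 77 in opposite directions, where independent lists share 39.5 and 31.6. All these contrasts use the same variance estimate for a gene, so genes with a small estimate tend to be called in both. The numbers for independent lists are thus too low a standard for these counts. Without the 2 libraries with atrial transcripts the first r was 0.121, and without Lhasa White 2 alone it was 0.0591.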

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

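The tests on GBP, on atrial transcripts and on cholesterol synthesis genes were chosen after those results were seen, except the tests of scaling and of the liver list median. Of 138 groups of 4 libraries examined for 1 library far from the other 3, 8 stood out, where chance gives 6.9. The groups overlap, since list means stand beside their own members, and MYH7 and BMP-10 were chosen after their values were seen. These counts thus cannot tell whether the outliers are due to chance. The number for each is the gap to the nearest library as a share of the range.

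Matrix genes had a mean of 1.09 in Lhasa White 2 against -0.39 to -0.14 in the other highland libraries (0.835). BMP-10 in Lhasa White 2 was at 8.18 on the log2 scale against 0.80 to 1.65 (0.885), and IRX4 at 4.11 against 6.04 to 6.19 (0.928). Contractile genes had a mean of 0.34 in Chahua 2 against -0.14 to -0.09 in the other lowland libraries (0.891), and TEK was at 2.74 there against 2.12 to 2.16 (0.933). Chahua 1 had 17245669 mapped reads against 19587417 to 20027198 (0.842). Reads in listed genes made up 93.0% in Linzhi Tibetan 1 against 96.3% to 96.6% (0.92), and 96.3% in Chahua 2 against 96.7% in the other lowland libraries (0.921).

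Atrial transcripts in Lhasa White 2 and Chahua 2 may come from how much atrial tissue was dissected, as a hypothesis. In Lhasa White 2 the ventricular IRX4 stood at 22.4% of the median of the 6 libraries without such transcripts, as a larger atrial share would give. In Chahua 2 the first test asked only that IRX4 lie below the range of those 6 libraries, which it did (61.7 against 64.9 RPKM, 85.1% of their median). A requirement that MYH15 also be low was added after seeing that MYH15 was highest in Chahua 2 (4949 RPKM), and since the markers point opposite ways the tissue share there stays open. Reads of Lhasa White 2 carried into Chahua 2 are argued against, because 13.6% of 22 genes found almost only in Lhasa White 2 had fewer reads in Chahua 2 than the MYH7 fraction requires (FMOD had 40 reads where 107 were needed). Sex is argued against by MYH7 at 3.56 RPKM or less in the other libraries with W-linked transcripts.

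GBP was low in both highland breeds. A difference in embryo sex is argued against, since the libraries with and without W-linked transcripts of one breed differed by at most 0.195 on the log2 scale, against -2.27 between highland and lowland. With the W-linked level as a covariate the difference was -2.21 with a standard error of 0.222, against 0.165 without it. The call ended as this error rose and residual degrees of freedom fell from 4 to 3, while the difference stayed close. The W-linked level is uneven over the breeds, which by itself widens the standard error. A wider spread between libraries was not shown. A drop of the whole interferon list near the size of the GBP difference is argued against by its median of 0.07 (0.0653). In that list 12 of 17 genes were higher in highland libraries. The test was set on a drop of that size, so a smaller or partial interferon difference stays open. A sequence or copy number variant against the reference cannot be told apart from lower expression, because 1 row of the table has a GBP symbol and no reads were used; a breed difference in expression stays open as well.

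Cholesterol synthesis genes were lower in Chahua than in White Leghorn. Sex is argued against by the White Leghorn libraries, of which 1 held W-linked transcripts and whose list means differed by -0.02 (-0.022), against -0.70 between the breeds. In Lhasa White the list mean was 0.36 in library 2, with W-linked transcripts, and -0.13 in library 1. That is the opposite direction to a lower level with W-linked transcripts, but library 2 also held atrial transcripts. Liver tissue in White Leghorn was first tested by the median difference of 20 liver genes, set to speak for it below -0.3 and against it above 0. That median was -0.03 (-0.0276) and decided nothing. A test on ALB, abundant in liver, was then chosen with that outcome known, and ALB at 2.77 RPKM or less in White Leghorn argues against liver tissue. Scaling is argued against by a list median of -0.61 (-0.608) or lower under both other scalings. Markers of proliferation (median -0.43), blood (-0.67) and matrix (0.49) differed between the same breeds, and whether cell makeup accounts for the cholesterol genes was not tested and stays open, as does a breed difference.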

How the results depend on the processing

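The W covariate, W-linked subsets, voom, the removal of both atrial libraries and the rescaling, and the alternatives to the other pairings and to the agreement beyond scaling, filter and pseudocount, and the test of the genes over splits, were chosen after seeing the data. The cause of a changed count was not tested unless given. A change in the correlation of up to 0.05 was taken as none, which was an own choice. The count of 1 gene between highland and lowland breeds became 0 without the low-value filter, with the replicate block, with the W-linked covariate, with voom, without the atrial libraries, with 2 groups of 4 and within libraries without W-linked transcripts, and lay between 0 and 1 with single libraries left out. Within libraries with W-linked transcripts it was 1, which is not GBP but ENSGALG00000022234, high in Lhasa White 2 (127 RPKM), the lone highland library there. The count of 1 between Lhasa White and Chahua became 0 with the replicate block, the covariate, voom, without the atrial libraries and with only the 4 libraries of the pair. Without the filter it was 4, without a variance trend 2, and with libraries left out 0 to 2. Without the filter 12 genes passed between Linzhi Tibetan and Lhasa White, 13 with Chahua, 12 with White Leghorn and 14 in any breed. Without a variance trend these were 2 between Linzhi Tibetan and Lhasa White, 1 between Linzhi Tibetan and White Leghorn, 3 between Lhasa White and White Leghorn and 3 in any breed. With only the pair's libraries 27 passed between Linzhi Tibetan and Chahua. Leaving out single libraries gave 0 to 53 between Linzhi Tibetan and Lhasa White, 0 to 30 between Lhasa White and White Leghorn, 0 to 1 in any breed and 0 to 52 in the other pairings. The highest of these came without Lhasa White 1, where Lhasa White 2 stands alone and is assumed to vary like the other breeds.

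The number of lists, 7, became 4 without the filter, 0 with an estimated correlation, 0 with fry and 2 to 7 with libraries left out. Of these 7 lists and directions, 1 was shared without Linzhi Tibetan 1, 5 without Linzhi Tibetan 2, 4 without Lhasa White 1, 2 without Lhasa White 2, 1 without Chahua 1, 5 without Chahua 2, 7 without White Leghorn 1 and 2 without White Leghorn 2. All 4 without the filter were shared, and 3 of 7 without the atrial libraries. The correlation of independent pairs ran from -0.439 to 0.0591 with libraries left out (0.0591 without Lhasa White 2) and reversed to 0.0252 with the covariate and to 0.121 without the atrial libraries. Deviations from the breed mean correlated between -0.332 and 0.170 across breeds for libraries of the same replicate number. Sex-linked and atrial differences enter these deviations, so a weaker pairing by replicate number cannot be excluded. The block changed no other count of genes or lists. For 36 differences of single genes other than GBP, 7 of 642 values took the other sign, in EPAS1, EGLN1 and HIF1A, and 0 passed. With 2 groups of 4, the real split called 0 genes, so that all 35 splits call at least as many by construction and their number says nothing about chance. The highest other split called 113 genes (34 without Z and W genes) and is the one that follows W-linked transcripts, which points to that signal as a structure of the samples. For lists, 27 of 35 splits called at least the 5 of the real one (highest other 9), so chance cannot be excluded for the lists.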

Other observations

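Some other genes were high in Lhasa White 2 and mostly also in Chahua 2, and were chosen after their values were seen. STMN2, a neuronal microtubule regulator, was at 32.2 RPKM there and 9.78 in Chahua 2, against 0.358 or less in the other libraries. GAP43, a growth cone protein, was at 12.7 and 2.93 RPKM against 0.905 or less, and TUBB3, a neuronal tubulin, at 20.7 and 3.52 against 2.04 or less. FMOD, a matrix proteoglycan, was at 26.8 RPKM in Lhasa White 2 and 0.777 in Chahua 2. OSTN, a muscle-secreted peptide, was at 22.8 and 28.1 RPKM in those libraries against 2.21 or less.

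Lhasa White 1 held ATP5A1W at 4.02 RPKM, which is 0.918% of the mean of the 4 libraries with W-linked transcripts, and HINTW at 4.26 RPKM. White Leghorn 2 held 0.241 and 0 RPKM of these.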
